A study of Mus musculus with 20 samples.

How the data were processed

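Lung RNA of 20 C57BL/6 mice was measured on 20 one-colour arrays of the MA11 type, 1 array per mouse. Per the labels, total RNA was labelled with the radioactive isotope 33P by reverse transcriptase after extraction with guanidinium thiocyanate, phenol and chloroform. Each array carried 9600 spots. Per the file headers, the deposited array files give each spot a median signal intensity and a median local background intensity, both on a linear scale and not normalised. The image software and the scanner settings are not given in the sources used here.

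The authors' processed intensity table of the whole series was compared with the array files line by line. In that deposited table, 100% of the values other than 1 constant equalled the signal intensity minus the background, divided by the median of that difference over the array, within a tolerance of 1e-04. The constant 0.002 made up 4.18% of the table, and 590 values were below 0. The table is therefore on a linear scale with each array's median at 1. The rule by which the authors chose values for the constant is not given in the sources used here. Values at the constant had signal over background ratios from 0.316 to 8.83, so the constant is not a simple signal threshold. Spots are identified by a running number, and the files do not pair these numbers with genes. Results are therefore given by spot, with at most 2 spots that rose and 2 that fell named per comparison, except where stated. Tests of gene lists fixed from the study's design, and averaging over the spots of a gene, were not run for the same reason.

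The labels name the treatment of each mouse, which gave 4 groups of 5 mice: untreated, flaxseed diet, thoracic radiation, and flaxseed diet with radiation. The mice carry separate numbers in the labels, so replicates are separate animals. Replicate numbers follow accession order and pair no mice across groups. No label or file gives an array lot, a hybridisation day or another batch.

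Signals were corrected for local background with the normexp method and an offset of 50, put on the log2 scale and quantile normalised between arrays. The linear model of limma 3.58.1 in R 4.3.3 was fitted to all 20 arrays with 1 coefficient per group. Moderated variances came from eBayes, and p-values were adjusted by the Benjamini-Hochberg method within each of 8 comparisons. A spot was called at an adjusted p under 0.05, with no filter on dim spots. A log2 fold change understates the change of dim spots because of the offset. Errors of fold changes are limma standard errors (SE), and errors of group means are standard deviations (SD) over 5 mice.

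The naming rule, fixed before the data were examined, took the 10 genes with the largest log2 increases and the 10 with the largest decreases among those called, with members of gene lists and a few fixed genes, and those with the smallest p where fewer than 3 were called. Because the spots have no gene names, the parts on lists and fixed genes were not applied. Of the others the first 2 of each direction were kept. Named spots were chosen on these same mice, so counts of mice beyond another group describe them and add no separate support. Some results were named outside the rule, after the values were seen. These were gene6080 with radiation averaged over diets, gene0020 for both treatments against untreated, and a neighbouring spot of gene0020. For both treatments against untreated, gene6080 fell under the rule.

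The procedure was tested on simulated intensities for 9600 spots with the means, spreads and backgrounds of these arrays, in which 200 spots were changed. The changed spots were drawn above a minimum mean level, so the recovery rates leave out the dimmest spots. Noise was drawn independently for each spot and array. On the real arrays, deviations from the group means correlated at 0.232 between spots 1 line apart in the file. The numbers of calls among unchanged spots therefore need not hold for the real arrays. For radiation against untreated, 63% of spots changed 1.5-fold and 95% of spots changed 2-fold were recovered, with 2 calls among unchanged spots. For flaxseed with radiation against flaxseed, 60% and 95% were recovered, with 9 calls among unchanged spots. For the interaction, 14% and 74% were recovered, with 8 calls among unchanged spots. No recovered spot had the wrong sign, with 0 in each of these comparisons.

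Measures of whole arrays were compared between groups with exact two-sided permutation tests, adjusted over 8 tests; with 5 against 5 mice the smallest p they can give is 0.00794. Alternatives fixed before the data were examined were no background correction, plain subtraction with a floor of 1, offsets of 10 and 200, 75th percentile scaling, cyclic loess, and 2 filters on dim spots. Further fixed alternatives were the authors' table on the log2 scale, array weights, a variance trend with robust fitting, a fit to the groups of the comparison alone, and leaving out each mouse. Alternatives added after seeing the data were a correction for position on the array, a correction for the place within 5 x 5 blocks of spots, array brightness as a covariate, and a floor of 0.05 for the authors' table. The position correction removed a running median over 15 x 15 spots, with the spots in file order taken as 80 rows of 120. That layout was inferred from the local background, whose log2 values correlated at 0.540 between spots 1 line apart in the file and at 0.531 between spots 120 lines apart. Figures were drawn with matplotlib 3.10.9.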

Results

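Gene expression was measured in the lungs of C57BL/6 mice, an inbred laboratory strain, 48 h after a single thoracic radiation dose of 13.5 Gy, after 21 days on a diet with 10% flaxseed, after both, or after neither. Each of the 4 groups held 5 mice with 1 array each. The median spot signal per array was 147 ± 35.6 in untreated mice, 204 ± 13.6 in mice on flaxseed, 152 ± 41.0 in irradiated mice and 141 ± 23.5 in mice given both (SD, n = 5 each). The median local background was between 19.7 and 35.8 on the 20 arrays, and between 97.6% and 98.7% of the spots were brighter than their background. The number of arrays limits the precision of each comparison. Correlations between the log2 values of 2 arrays ranged from 0.938 to 0.981, and no array pair held identical values.

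The effect of radiation in mice without flaxseed was addressed by comparing irradiated with untreated mice. Of 9600 spots, 1 rose and 4 fell (limma, adjusted p under 0.05), and 2 of those that fell changed at least 2-fold. The spot gene2313 fell by 1.69 on the log2 scale (SE 0.304, adjusted p = 0.0380), from 10.00 ± 0.28 in untreated to 8.31 ± 0.44 in irradiated mice. The spot gene0020 fell by 1.43 (SE 0.154, adjusted p = 5.24e-05), from 7.88 ± 0.26 to 6.45 ± 0.13. The spot that rose, gene2754, went from 6.55 ± 0.08 to 7.16 ± 0.22, a log2 difference of 0.61 (SE 0.108, adjusted p = 0.0379). In each of these 3 spots, all 5 irradiated mice lay beyond all 5 untreated mice. At an unadjusted p under 0.05 there were 1070 spots, against 480 expected by chance. The count of 5 was 17 without untreated replicate 4, 10 without radiation replicate 3, and 2 or 3 without untreated replicate 1, 2, 3 or 5 or radiation replicate 2, 4 or 5. It was 13 with 75th percentile scaling, of which 12 fell. The fall of gene0020 was not called with plain background subtraction (-2.73, limma adjusted p = 0.212). Nor was it called on the authors' table with its low values at the constant (-2.66, limma adjusted p = 0.392). Its size was larger in these settings than in the main fit, and -0.71 with an offset of 200. Leaving out 1 mouse ended the calls of gene2754 and gene2313 in 8 of 10 fits each. In other settings gene2754 was not called in 3 of 15 and gene2313 in 4 of 16. The rise of gene2754 ranged from 0.27 to 1.35 over those settings.

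Radiation in mice on flaxseed was addressed by comparing mice given both treatments with mice on flaxseed alone. Here 488 spots rose and 349 fell, together 837, of which 20 rose and 29 fell at least 2-fold. The median size of a called change was 0.61 on the log2 scale. The spot gene4027 fell by 2.45 (SE 0.371, adjusted p = 0.000741), from 12.83 ± 0.54 to 10.38 ± 0.91. The spot gene2263 fell by 2.27 (SE 0.442, adjusted p = 0.00321), from 13.54 ± 0.78 to 11.27 ± 1.05. The spot gene0020 rose by 1.28 (SE 0.154, adjusted p = 0.000156), from 6.32 ± 0.35 to 7.59 ± 0.24. Its flaxseed signals were near the local background in 2 of 5 mice, and the size of this rise was 0.58 with an offset of 200 and 4.02 on the authors' table. The spot gene1904 rose by 1.20 (SE 0.266, adjusted p = 0.00740), from 11.96 ± 0.56 to 13.16 ± 0.35. All 5 mice given both treatments lay beyond all 5 mice on flaxseed in gene4027, gene0020 and gene1904, and 4 of 5 did in gene2263. Most calls fell on bright spots, with 524 of the 837 in the 25% of spots with the highest mean level. The share of called spots that rose was 58.3%, and it was 78.4% with 75th percentile scaling, which gave 760 higher and 209 lower spots.

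**Figure D1:**
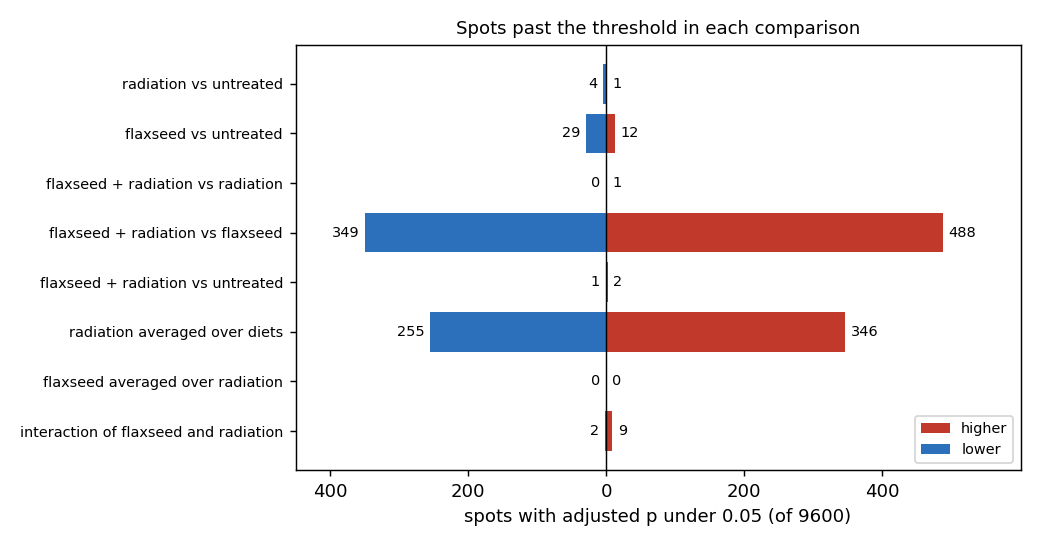
Number of spots, of 9600, with an adjusted p under 0.05 in each of the 8 comparisons; bars to the right count spots that were higher in the first-named condition and bars to the left spots that were lower, each with its count. The comparison of mice given both treatments with mice on flaxseed alone has 488 and 349 spots, and radiation without flaxseed has 1 and 4.

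Averaged over the diets, 346 spots were called higher and 255 lower in the 10 irradiated than in the 10 unirradiated mice, together 601. The 5 flaxseed arrays among the unirradiated stood apart from all others on the first principal component, with scores of 7.54 to 25.2, and 5 spots were called without flaxseed against 837 on flaxseed. The median size of a called change was 0.43 on the log2 scale. No spot rose by as much as 2-fold, a count of 0, and 14 spots fell at least 2-fold. The spot gene2263 fell by 2.26 (SE 0.312, adjusted p = 0.000397), and its group means were 13.16 ± 0.52 in untreated, 13.54 ± 0.78 in flaxseed, 10.91 ± 0.65 in irradiated and 11.27 ± 1.05 in doubly treated mice. The spot gene4027 fell by 2.16 (SE 0.263, adjusted p = 0.000119), with 12.12 ± 0.38, 12.83 ± 0.54, 10.25 ± 0.65 and 10.38 ± 0.91 in the same order. The spot gene8822 rose by 0.81 (SE 0.139, adjusted p = 0.00168) and gene7721 by 0.75 (SE 0.123, adjusted p = 0.00130). The means of gene8822 were 13.05 ± 0.24, 12.21 ± 0.22, 13.58 ± 0.18 and 13.30 ± 0.56 in that order, a radiation difference of 0.53 without flaxseed and 1.10 with it. Those of gene7721 were 13.02 ± 0.22, 12.54 ± 0.35, 13.58 ± 0.23 and 13.49 ± 0.35, a difference of 0.56 without flaxseed and 0.95 with it. In each of these 4 spots all 10 irradiated mice lay on the changed side of the mean of the 10 others. All 10 others lay on the opposite side of the irradiated mean. The 4 spots were chosen on these mice, so this separation adds no separate support. The mean log2 level of the 14 spots lowered at least 2-fold, which were chosen on these mice, was 11.28 ± 0.20 in untreated, 11.76 ± 0.37 in flaxseed, 9.99 ± 0.23 in irradiated and 10.01 ± 0.46 in doubly treated mice. The share of called spots that rose was 57.6%, and 76.5% with 75th percentile scaling, with 515 higher and 158 lower.

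**Figure D2:**
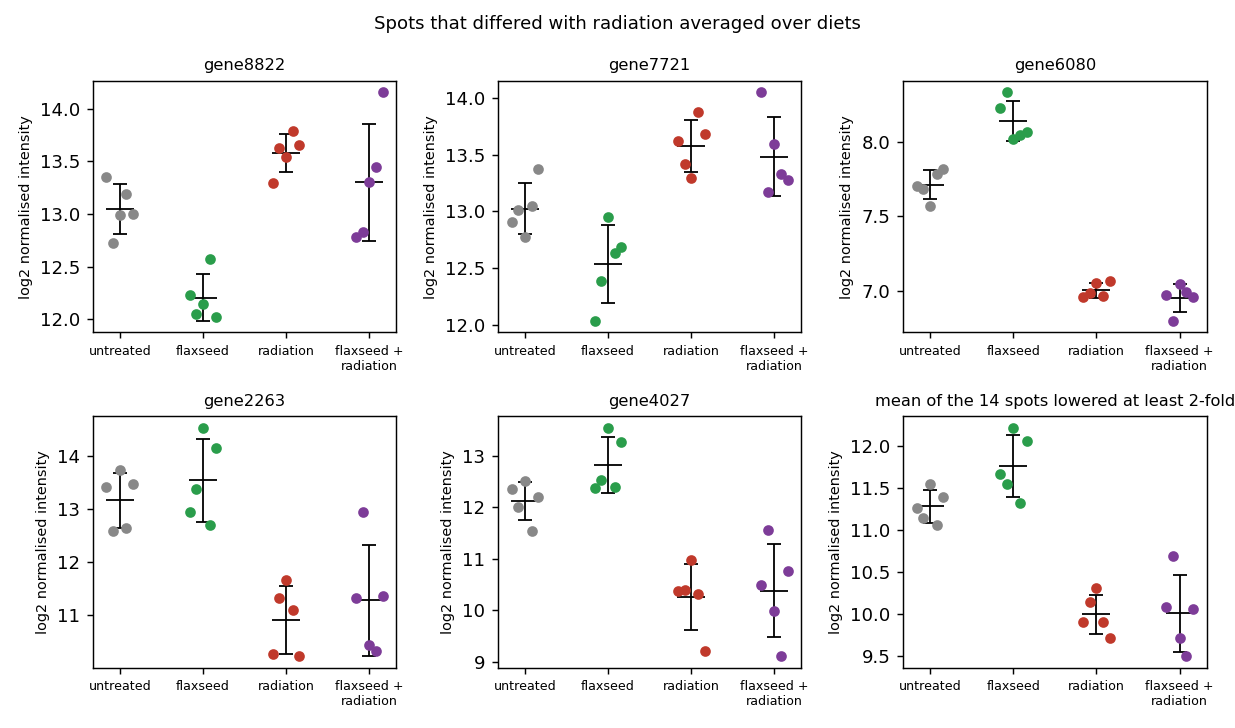
Normalised log2 intensity in each mouse (points) with the group mean and SD (bars, n = 5) for 5 spots that differed with radiation averaged over diets, and for the mean of the 14 spots lowered at least 2-fold; the vertical axes do not start at 0. The spot gene4027 averages 12.12 and 12.83 without radiation and 10.25 and 10.38 with it.

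The 2 comparisons of irradiated with unirradiated mice, without and with flaxseed, share no array. Across the 9600 spots, which are not independent replicates, their log2 fold changes correlated with Pearson's r = 0.306 and Spearman's rho = 0.216. Of the 837 spots called on flaxseed, 640 had the same sign without flaxseed, or 76.5%. Their median change was 0.61 in size on flaxseed and 0.13 in the same direction without it. When the labels of the untreated and irradiated mice were split in other ways, 11 of 100 splits, the real one included, gave a correlation as far from 0, and 17 gave as large a share of 1 sign. Of the 488 spots that rose on flaxseed, 1 was also called higher without flaxseed, where independent lists would share 0.0508. Of the 349 that fell, 2 were also called lower, where independent lists would share 0.145.

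**Figure D3:**
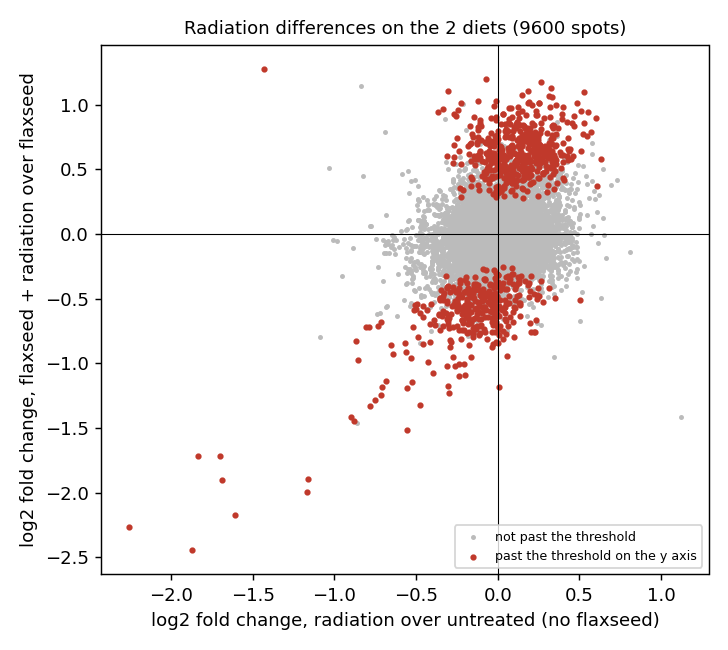
Log2 fold change of each of 9600 spots with radiation in mice without flaxseed (horizontal axis) and in mice on flaxseed (vertical axis), with the 837 spots called on the vertical axis in red. Of these 837 spots, 640 have the same sign on both axes, and gene0020 lies at -1.43 on the horizontal and 1.28 on the vertical axis.

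The effect of flaxseed alone was addressed by comparing mice on flaxseed with untreated mice. Here 12 spots rose and 29 fell, together 41, and 2 of those that fell changed at least 2-fold. The spot gene0020 fell by 1.57 (SE 0.154, adjusted p = 2.34e-05), from 7.88 ± 0.26 to 6.32 ± 0.35. Its flaxseed signals were near the local background, at 30.1 over a background of 36.7 in replicate 1 and 29.3 over 24.9 in replicate 2, and at 61.8 to 92.9 in the other 3 mice. The size of this fall depended on the treatment of low values, from -0.75 with an offset of 200 to -4.42 on the authors' table. The spot gene9181 fell by 1.13 (SE 0.236, adjusted p = 0.0374), from 8.90 ± 0.17 to 7.77 ± 0.65. The spot gene3936 rose by 0.77 (SE 0.150, adjusted p = 0.0273), from 9.36 ± 0.21 to 10.13 ± 0.42, and gene4563 rose by 0.71 (SE 0.142, adjusted p = 0.0273), from 7.68 ± 0.35 to 8.39 ± 0.26. All 5 mice on flaxseed lay beyond all untreated mice in gene0020, gene9181 and gene4563, and 4 of 5 did in gene3936. The count of 41 was 1 with only these groups in the fit and 108 with 75th percentile scaling, of which 93 fell. It was 5 without untreated replicate 1, 14 without untreated replicate 5, 26 without untreated replicate 4, 10 and 24 without flaxseed replicates 1 and 2, and 103 without flaxseed replicate 5. Leaving out 1 mouse ended the call of gene9181 in 8, of gene4563 in 6 and of gene3936 in 4 of 10 fits. In the 16 other settings gene3936 was not called in 5, gene9181 in 4 and gene4563 in 3.

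Flaxseed in irradiated mice was addressed by comparing mice given both treatments with irradiated mice. The 1 called spot was gene0020, which rose by 1.14 (SE 0.154, adjusted p = 0.00344), from 6.45 ± 0.13 to 7.59 ± 0.24. All 5 mice given both treatments lay above all 5 irradiated mice. The irradiated signals of gene0020 were low, at 33.4 to 68.5, where the offset narrows the SD. No spot was called lower, a count of 0 with limma. The lower spots with the smallest p were gene8217 and gene5130, with log2 differences of -0.64 (SE 0.134) and -0.40 (SE 0.084) and an adjusted p of 0.261 for both. At an unadjusted p under 0.05 there were 717 spots. The call of gene0020 was not made with plain background subtraction (limma adjusted p = 0.560) or on the authors' table (limma adjusted p = 0.492, and 0.117 with its floor at 0.05). The rise was larger there than in the main fit, at 2.32 with plain subtraction and 2.26 on the authors' table. With an offset of 200 it was 0.54.

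Mice given both treatments were also compared with untreated mice. The spots gene4106 and gene2120 rose by 0.77 (SE 0.135) and 0.50 (SE 0.086), both with an adjusted p of 0.0437. The third called spot, gene6080, fell by 0.76 (SE 0.076, adjusted p = 2.96e-05). Its levels were 7.71 ± 0.10 in untreated, 8.14 ± 0.14 in flaxseed, 7.00 ± 0.05 in irradiated and 6.95 ± 0.09 in doubly treated mice. With radiation averaged over diets, gene6080 had a log2 difference of -0.95 (SE 0.054) and the lowest limma adjusted p of that comparison (1.13e-09), and all 10 irradiated mice lay below all 10 others. Its size depended on the processing, although the call was kept. Over the other settings it ranged from -1.47 to -0.52 averaged over diets, and from -1.29 to -0.40 for both treatments against untreated. In gene4106, gene2120 and gene6080, all 5 mice given both treatments lay beyond all 5 untreated mice. At an unadjusted p under 0.05 there were 725 spots. The count of 3 was 18 without the second mouse given both treatments, and 1 without untreated replicate 2 or without any 1 of the other 4 mice given both treatments. Leaving out 1 mouse ended the calls of gene4106 and gene2120 in 8 of 10 fits each. In the 16 other settings gene2120 was not called in 9 and gene4106 in 5.

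Averaged over radiation, with 10 mice on flaxseed and 10 without, limma called 0 spots, the lowest adjusted p being 0.315. At an unadjusted p under 0.05 there were 714 spots, against 480 expected by chance. The spots with the smallest p were gene3056, with a log2 difference of 0.31 (SE 0.067), and gene0384, with 0.38 (SE 0.083), both higher on flaxseed in the samples measured. The lower ones were gene9020 and gene8762, with -0.59 (SE 0.118) and -0.34 (SE 0.071). None of these 4 spots passed the threshold, each with an adjusted p of 0.315. The count was 1 without untreated replicate 3 or without the fifth mouse given both treatments, and 2 without flaxseed replicate 4.

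Whether the radiation difference differed between the diets was tested as the interaction of flaxseed and radiation. It was called for 11 spots, 9 with a positive and 2 with a negative interaction. In gene0020 the radiation difference was -1.43 without flaxseed and 1.28 with it, an interaction of 2.71 (SE 0.217, adjusted p = 7.04e-07). Its level after both treatments differed from the untreated level by -0.29, which did not pass the threshold (SE 0.154, adjusted p = 0.709). The size of the interaction depended on the treatment of low values, from 1.29 with an offset of 200 to 6.68 on the authors' table. In gene7134 the interaction was 1.41 (SE 0.261, adjusted p = 0.0373), with means of 9.46 ± 0.12 in untreated, 8.53 ± 0.38 in flaxseed, 9.15 ± 0.28 in irradiated and 9.63 ± 0.39 in doubly treated mice. The negative interactions were -0.999 in gene8217 (SE 0.189, adjusted p = 0.0408) and -0.85 in gene3400 (SE 0.150, adjusted p = 0.0322). At an unadjusted p under 0.05 there were 1280 spots. The count of 11 was 73 on the authors' table and 30 with 75th percentile scaling, and 35 without flaxseed replicate 5. It was between 2 and 6 without any 1 of untreated replicates 1, 3, 4 and 5, flaxseed replicate 2, radiation replicates 2 and 5, and replicates 1, 3, 4 and 5 of the mice given both treatments. Leaving out 1 mouse ended the call of gene8217 in 16, of gene7134 in 13 and of gene3400 in 6 of 20 fits, and gene8217 was not called in 7 of 15 other settings; gene0020 was called in all 20 fits and in all 14 settings that tested it.

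**Figure D4:**
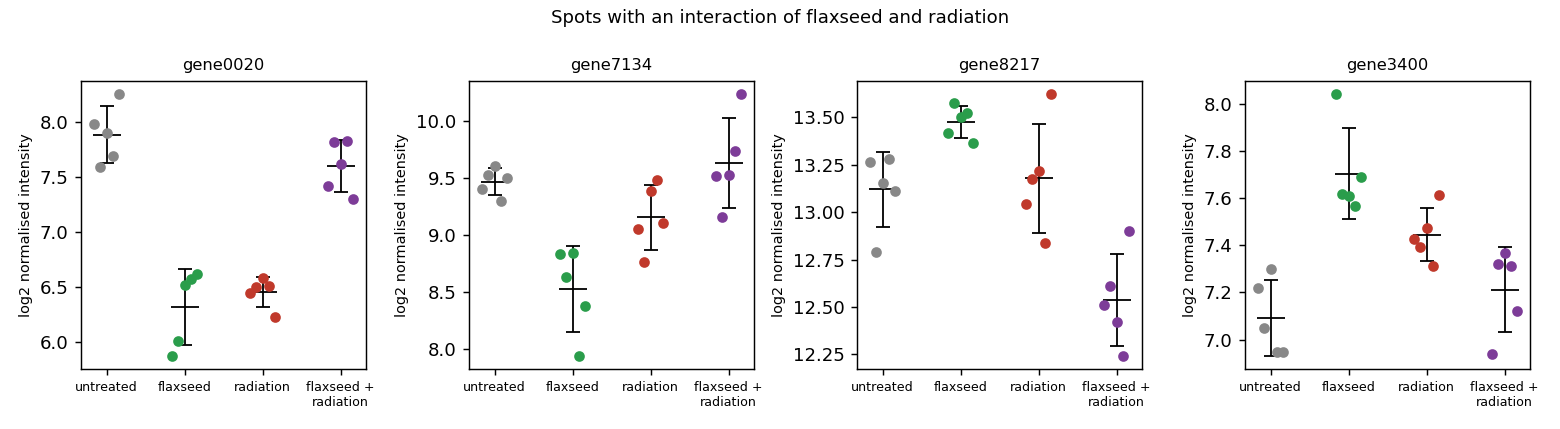
Normalised log2 intensity in each mouse (points) with the group mean and SD (bars, n = 5) for the 4 named spots with an interaction of flaxseed and radiation; the vertical axes do not start at 0. In gene0020 the untreated mean of 7.88 and the mean of 7.59 after both treatments lie above the means of 6.32 and 6.45 after 1 treatment.

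The arrays of mice on flaxseed alone stood apart from the rest. Scores on the first principal component, which held 20.1% of the variance, ranged from 7.54 to 25.2 for the flaxseed arrays, from -7.14 to 6.50 for untreated mice, from -16.2 to -3.24 for irradiated mice and from -14.5 to -3.94 for mice given both. The flaxseed scores differed from those of untreated mice and of mice given both treatments (exact permutation p = 0.00794 for each, the smallest possible, adjusted p = 0.0212). Irradiated and untreated mice did not pass the adjusted threshold (exact permutation p = 0.0317, adjusted p = 0.0508). The flaxseed arrays were also the brightest group, with a median background-subtracted signal of 172 ± 12.7 against 120 ± 32.0 in untreated mice and 112 ± 20.5 in mice given both (SD, n = 5). These differences had exact permutation p-values of 0.0238 (adjusted p = 0.0476) and 0.00794 (adjusted p = 0.0212). The correlation of flaxseed replicate 4 with its group was the lowest of all arrays at 0.961. Without it, 647 spots differed between mice given both treatments and mice on flaxseed, 566 with radiation averaged over diets, and 10 in the interaction. Between flaxseed and untreated mice there were 31 without it, of which 18 were higher and 13 lower, against 12 and 29 with it. Of the 647, 566, 10 and 31 spots called without it, 577, 499, 7 and 21 were also called with it.

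**Figure D5:**
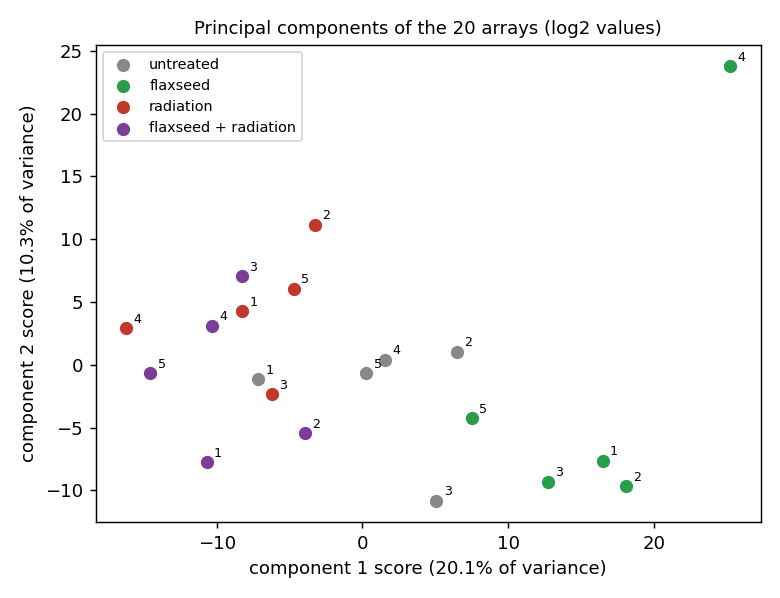
Scores of the 20 arrays (points, numbered by replicate and coloured by group) on the first and second principal components of the normalised log2 values, which hold 20.1% and 10.3% of the variance. The 5 flaxseed arrays lie at first-component scores of 7.54 to 25.2, and flaxseed replicate 4 lies at 23.8 on the second component.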

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

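For the flaxseed arrays, the tests on position on the array, on the place within the 5 x 5 blocks and on a diet effect that is the same with and without radiation were chosen only after the results they bear on were seen, as were the tests of gene0020 on neighbouring spots and local background.

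The arrays of mice on flaxseed alone stood apart, with 837 spots called against mice given both treatments. The highest of the 99 other splits of these 10 mice gave 27. The real split was the only 1 of 100 with as many, which argues against chance. With log2 array brightness in the model the called log2 fold changes had 1.11 times their size (range 1.07 to 1.13 leaving out each array). This argues against an effect of brightness like that between arrays of the same group. Median background-subtracted signals did not overlap between the groups, at 158 to 184 in flaxseed and 84.6 to 138 in doubly treated mice. Brightness that follows the groups therefore cannot be told apart from the treatments. In the model with brightness, 532 of the 837 spots were called. The 305 others kept a median size of 0.51 against 0.52, while their median SE went from 0.139 to 0.185. After removal of the running median over the array surface 96.1% of the 837 spots were called. After removal of the median of the spots at the same place in their 5 x 5 block 91.2% were, but that correction could end few calls. The median log2 fold change at each of the 25 places lay between -0.0644 and 0.0386, against a median called size of 0.61. The share of called spots that rose ranged from 19.0% to 93.9% over the places, so an effect of the place remains open. Leaving out each of the 10 arrays gave at least 601 calls, so no single array accounts for the pattern. A diet effect that is the same with and without radiation cancels between these groups, both on flaxseed, so it cannot give the 837 calls. The differences between flaxseed and no flaxseed, without and with radiation, correlated at -0.180 across spots, lower than in all but 1 of 99 label shuffles. Apart from the 837 calls, that argues against a shared diet effect as the main pattern over all spots. It cannot exclude a shared diet effect in part of the spots. The difference in median background-subtracted signal was 51.5 for flaxseed against untreated mice and -13.1 for doubly treated against irradiated mice. The correlation was not adjusted for brightness. Flaxseed against untreated gave 41 calls and both treatments against untreated 3, and mean first-component scores were 16.0 in flaxseed, 1.26 in untreated and -9.55 in doubly treated mice, so part of the difference may lie in the doubly treated arrays; a radiation effect in mice on flaxseed, a diet effect present only without radiation, and a processing batch that follows the groups remain open, and since no label or file gives a batch, it cannot be told apart from the treatments.

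The 14 spots that fell at least 2-fold with radiation averaged over diets varied together on average between mice of the same group, though not all of them: 11 had a positive mean correlation with the rest and 3 a negative one, from -0.200 to -0.0874. The mean pairwise correlation of their deviations from the group means was 0.295 (0.262 to 0.326 leaving out each array), above the highest of 1000 random sets matched on level and spread, 0.190, which argues against general variation between arrays. It was 0.289 after regression on array brightness and 0.300 after the correction for position, so neither brightness nor broad position on the array accounts for it. Of the 14 spots, 10 lay in the middle column of their 5 x 5 block, where even spreading gives 2.8. The random sets were not matched on the place in the block, and no correction for it was applied to this correlation. A shared regulation of part of these transcripts, spots that hold copies of 1 transcript, or an effect of the place in the block may account for the pattern. None of these was tested, and the files do not pair spots with genes.

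In gene0020 the interaction of flaxseed and radiation was 2.71, the test of the difference itself. The largest interaction of the same sign among its 8 neighbouring spots was 0.102 of that size, which argues against signal added from a neighbouring spot. The neighbour gene0024 had an interaction of -2.54 (limma adjusted p = 0.198), close in size and opposite in sign, which added signal does not give and which was not explained. Leaving out each of the 20 arrays gave at least 2.59, so no single array accounts for it. Without background correction the interaction was 4.04, so it does not arise from the subtraction of local background. That setting also left out the offset. With background correction and an offset of 10 the interaction was 4.08, so the larger size says nothing about the background. The size ranged from 1.29 to 6.68 with the treatment of low values. A response of this transcript to each single treatment that is not seen after both, and a difference in this spot between array lots that follow the groups, remain open; the labels give no lots.

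The interaction was called for 11 spots, in which the difference between irradiated and unirradiated arrays differed between the diets; 2 of these 11 were called with array brightness as a covariate. The other named ones were gene7134 at 1.41, gene8217 at -0.999 and gene3400 at -0.85.

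Several single arrays stood far from the other 4 of their group relative to the range of the group. Untreated replicate 1 had a median signal of 210 against 123 to 140 in the others, and a median background-subtracted signal of 177 against 98.5 to 111. Flaxseed replicate 4 correlated with its group at 0.961 against 0.975 to 0.976, and had a second-component score of 23.8 against -9.68 to -4.25. The fifth mouse given both treatments correlated with its group at 0.972 against 0.976 to 0.978. Untreated replicate 3 had a second-component score of -10.8 against -1.14 to 1.05. In gene3400, flaxseed replicate 1 had a log2 value of 8.04 against 7.57 to 7.69. Of 36 array-level group tests 6 stood apart in this way, where chance gives 1.8, and of 88 tests of named spots 1 did, where chance gives 4.4. The array-level tests are not independent. Untreated replicate 1 was counted for both of its signal measures, and flaxseed replicate 4 for both its correlation and its component score. The 6 may therefore overstate the excess over 1.8.

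Other splits of the same mice were counted for each comparison, 100 each with the real one. The real split was the only 1 with as many for radiation against untreated (5 spots, highest other split 3) and flaxseed against untreated (41, highest other 3). So it was for both treatments against untreated (3, highest other 1), radiation averaged over diets (601, highest other 2) and the interaction (11, highest other 2). The real split was also the only 1 for both treatments against radiation (1, highest other 0), where the result rests on the single spot gene0020. These ranks argue against chance but do not exclude it. For radiation averaged over diets, radiation labels were exchanged within each diet, so a difference on flaxseed alone could give its rank. For the interaction, diet labels were exchanged within irradiated and within unirradiated mice. Those splits stand for no diet effect of any kind, so the rank does not test the interaction alone. With 100 splits no share below 1 in 100 can be shown, and the ranks were not adjusted over the 8 comparisons. The counts of 5, 3 and 1 lay close to the highest other split. For flaxseed averaged over radiation the real count was 0 and the highest other 1; all 100 splits must reach a count of 0, so the splits decide nothing there. For the correlation of 0.306 between the 2 radiation comparisons, 11 of 100 splits were as far from 0, the highest other being 0.411, so chance is not excluded.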

How the results depend on the processing

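Chosen only after seeing the data were the corrections for position on the array and for the place within 5 x 5 blocks. So were array brightness as a covariate and the floor of 0.05 for the authors' table. The cause was not tested for any change given here. A filter changes the number of tests by construction, and a fit to fewer groups changes the mice that set the spread. Whether that accounts for a change in count was not tested. The fit to fewer groups gave 11 instead of 5 for radiation against untreated and 1 instead of 41 for flaxseed against untreated. For mice given both treatments against flaxseed the count of 837 lay between 610 and 1057 under the alternatives and between 601 and 918 leaving out each mouse; 328 of the 837 spots were called under all planned settings other than leaving out a mouse, and 453 in all 10 leave-one-out fits. For radiation averaged over diets the count of 601 lay between 406 and 805, and between 414 and 729 leaving out each mouse; 262 spots were called under all planned settings other than leaving out a mouse, and 384 in all 20 leave-one-out fits. The other counts were small and moved by over 1.5 times in many settings. Leaving out each mouse gave 2 to 17 for radiation against untreated, 5 to 103 for flaxseed against untreated, 1 in each fit for both treatments against radiation, 1 to 18 for both against untreated, 0 to 2 for flaxseed averaged over radiation and 2 to 35 for the interaction.

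For radiation against untreated (5 spots) the count was 14 without background correction, 2 with plain subtraction, 13 and 2 with offsets of 10 and 200, 13 with 75th percentile scaling, 15 in the 50% of spots with the higher mean level (the brighter spots), 3 on the authors' table, 10 with the variance trend, 11 with these groups alone in the fit and 25 after the correction for position. For flaxseed against untreated (41) it was 10 with plain subtraction, 108 with 75th percentile scaling, 62 with cyclic loess and 65 in the brighter spots. It was 103 on the authors' table, 116 with its floor at 0.05 and 1 with these groups alone. After the correction for position it was 105. With brightness it was 26, of which 15 were among the 41. For both treatments against radiation (1) it was 0 with plain subtraction (709 at an unadjusted p under 0.05), 0 in the brighter spots (285), 0 on the authors' table (932) and 0 with its floor at 0.05 (975). For both treatments against untreated (3) it was 16 without background correction, 1 with plain subtraction, 7 with an offset of 10, 16 in the brighter spots, 5 on the authors' table and 6 with its floor at 0.05, 5 with the variance trend, 12 after the correction for position, 1 after that for the place in the block and 1 with brightness. For flaxseed averaged over radiation (0) it was 1 after the correction for position. For the interaction (11) it was 6 with plain subtraction, 6 with an offset of 200, 30 with 75th percentile scaling, 6 in the brighter spots, 73 on the authors' table and 136 with its floor at 0.05, 31 after the correction for position and 4 with brightness.

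Of the named spots' log2 fold changes, 934 values under other settings kept their sign and side of the threshold. A further 142 kept the sign and lost the call, 3 gained a call, and none changed sign. The 934 include values of spots not called in the main fit that stayed uncalled. They also include gene0020 and gene6080 in several comparisons each. The 934 therefore overstate how stable the calls of the other named spots were. Not run were the gene list tests and the mean over the spots of a gene, since the files do not pair spots with genes, and a batch block, since no batch is given; a fit to the groups of the comparison alone is the same as the given fit for the 3 comparisons that use all 4 groups. Few calls fell on dim spots, with 38 of 837 in the 25% of spots with the lowest mean level, and the reason was not tested.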

Other observations

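The test given here was chosen only after the result was seen. The running spot numbers follow 384 blocks of 5 x 5 spots, so each of the 25 places within a block is held by 384 spots spread over the array. Among the 837 spots called between mice given both treatments and mice on flaxseed, the share that rose ranged from 19.0% at place 5 to 93.9% at place 10. Shuffling directions among the called spots 100000 times gave no chi-square as large as the observed 164, the highest being 63.6 (permutation p = 1e-05, the smallest possible). With radiation averaged over diets the chi-square was 148 and the highest shuffled one 67.2 (permutation p = 1e-05). Spots are not independent replicates, and the place explained 2.98% of the variance of the log2 fold changes between mice given both treatments and mice on flaxseed.

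Of the 14 spots that fell at least 2-fold with radiation averaged over diets, 10 lay in the middle column of their block, where even spreading gives 2.8, and 5 lay at place 13, where even spreading gives 0.56. These counts were noticed in the data and were not tested. Across the 25 places, the mean log2 fold changes with radiation on flaxseed and without it, which share no array, correlated at 0.589, and 35 of 100 splits of the untreated and irradiated mice gave a correlation as far from 0, the highest other being 0.826. What the places stand for in the printing of the arrays is not given in the sources used here.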
